A study of Mus musculus with 15 samples.

How the data were processed

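Poly(A) RNA from splenic CD8+ T cells of OT-I mice was sequenced as paired ends on a NovaSeq instrument after a stranded library preparation, per the labels' protocols. OT-I mice carry a transgenic T cell receptor that recognises the ovalbumin peptide OVA257-264. The cells came from wild-type (WT) or Susd2-/- mice. At day 0 the cells were untreated, and at day 3 they came from splenocytes cultured with the peptide. In both cases they were enriched with magnetic beads by removal of other cells, so the libraries can hold some RNA of other spleen cells.

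The deposited table held raw gene counts, whole numbers with no normalization, in 15 columns for 27019 gene symbols, per the file header and the values. The submitters' processing notes name fastp 0.23.2, HISAT2 2.1.0, SAMtools 1.10, Subread 2.0.1 and the GRCm38 build, without roles or order. The annotation release, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. Counts of genes with near-identical copies (ribosomal protein genes and their pseudogenes, H2-Q, Klra, Gbp and V segment families, mitochondrial genes with nuclear copies) and of genes overlapped by an antisense gene are therefore uncertain.

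Each column was 1 sequencing lane of a library. There were 8 libraries in 4 groups of 2, and 7 of the libraries had 2 lanes and 1 (WT day 3, library 2) had 1 lane. Lanes of a library were summed, and the library was the unit of replication. The lanes of a library differed by a chi-square per degree of freedom of 3.01 to 3.17 over genes with at least 20 counts in the 2 lanes together. The same statistic between the 2 libraries of a group was 3.37 for WT day 0, 6.30 for Susd2-/- day 0, 12.5 for WT day 3 and 16.0 for Susd2-/- day 3. The WT day 0 libraries thus differed little more than lanes did, and a fit that counts the day 0 libraries of each group as 1 was added after seeing the data. The labels do not say that libraries of a group came from separate mice, so the p-values measure only the spread between these libraries, which may be technical. In every lane, genes with a count of 2 outnumbered genes with a count of 1, by 1.69 to 2.04 times, so the counts are not independent fragments. Intervals from counts and floors of 3 counts assume independent counts, so the intervals are too narrow and the folds given as bounds may be too large, and neither covers the spread between mice.

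Library totals ran from 26829807 to 53846911 counts. Genes were kept by edgeR's filterByExpr on the 4 groups, which left 16057 genes and at least 99.9% of the counts of each library. All 4 groups were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM normalization, glmQLFit and the robust quasi-likelihood F test, with 4 residual degrees of freedom before pooling across genes. The p-values were adjusted by the Benjamini-Hochberg method over the 16057 genes within a comparison, and an adjusted p below 0.05 is what is meant by a change, a rise or a fall. The comparisons were Susd2-/- against WT at day 0 and at day 3, day 3 against day 0 in each genotype, and the interaction of genotype and day. Levels are given as edgeR's CPM, counts scaled to a common total by TMM-scaled library sizes, as mean ± SD over the 2 libraries of a group. Effects are given as log2 fold changes ± standard error (SE), the SE being the fold change divided by the square root of the F statistic. Every adjusted p in the text is edgeR's unless another test is named.

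The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took Susd2, up to 12 rising and 12 falling genes of the largest fold change for each genotype comparison and up to 10 of each for the day comparisons. These had to be past the test, at an average log2 CPM of at least 1 and with both libraries of one group above both of the other. It also took the 10 interaction genes of smallest adjusted p, up to 4 members of smallest adjusted p from each list and up to 2 from lists without a call. Symbols of predicted genes, Riken clones and numbered pseudogenes were left out of the naming, not of the counts. The text names a part of the genes the rule gave. The 37 lists, 36 of which could be tested with limma 3.58.1 (1 had a single measured member), cover T cell states and functions, proliferation, metabolism, ribosomes, interferon and stress responses, genes next to Susd2, CD8 T cell identity, the OT-I receptor segments and markers of other cell types. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 36 lists.

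The procedure was tested on simulated counts for the 16057 genes with 200 changed genes. Counts were drawn from each gene's mean over all 8 libraries, 1 fitted spread per gene and the libraries' depths. The simulation thus held neither the differences between the days nor a difference in spread between them, and few genes changed. Its rates may therefore not hold for the real data. For Susd2-/- against WT at day 0, 44% of genes changed 1.5-fold, 64% of those changed 2-fold, 84% of those changed 4-fold and 96% of those changed 8-fold were recovered, and 14.3% of the calls were false. For the same contrast at day 3 these values were 46%, 62%, 80%, 92% and 9.68%. For the WT day comparison 92% of 8-fold changes were recovered with 4.17% false calls, for the Susd2-/- day comparison 78% with 10.3%, and for the interaction 86% with 7.35%. The share of false calls thus came out above the nominal 5% in 4 of the 5 simulated comparisons.

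Alternatives covered the unit of replication (lanes as samples, or as a random block in limma voom), the lanes used, the test (DESeq2 1.42.0, limma voom), the scaling (RLE factors, total counts), the low-count filter, the libraries in the fit, each library left out in turn, the library number as a block, stricter thresholds, and the removal of mitochondrial, receptor segment and sex-linked genes. Added after seeing the data were the day 0 libraries counted as 1 per group, lane 2 alone, removal of a trend on transcript length and GC content (known for 98.9% of the tested genes), and leaving out libraries in the list tests. Gene positions are from GENCODE M21 on GRCm38, in which 26293 of the symbols were found, with 429 more through RefSeq synonyms and 297 not found.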

Results

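Transcript levels were measured in 8 libraries of splenic CD8+ T cells from OT-I mice, with 2 libraries in each of 4 groups (WT day 0, Susd2-/- day 0, WT day 3 and Susd2-/- day 3). Susd2 encodes a membrane protein with a sushi domain. Library totals were 30323080 and 27750718 counts for WT at day 0, 29482458 and 26829807 for Susd2-/- at day 0, 33385488 and 30257547 for WT at day 3, and 31671266 and 53846911 for Susd2-/- at day 3. The first principal component of log2 CPM separated the days and held 89.6% of the variance, and the second held 3.84%. The spread between the 2 libraries of a group was lower at day 0 (biological coefficient of variation 5.38%) than at day 3 (10.1%). Trbv12-1, the segment of the OT-I receptor beta chain, made up 99.2% to 99.8% of Trbv counts in every library.

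Susd2 lies on the minus strand of chromosome 10 at 75636706 to 75644008 (GRCm38). It had 90 and 80 counts in the WT libraries at day 0 and 1 and 3 counts in the Susd2-/- libraries, and 16 and 10 counts against 0 and 2 counts at day 3. By total counts, the Susd2-/- level was 2.43% of WT at day 0 (exact 95% interval 0.654% to 6.33%, which assumes independent counts and is too narrow where they are not) and 5.72% at day 3 (0.658% to 22.9%). Susd2 fell in Susd2-/- cells at day 0 (adjusted p = 2.32e-05). At day 3 it did not pass the test (adjusted p = 0.112), with 0.479 and 0.33 CPM by total counts in the WT libraries, but it passed without WT library 2 of day 3 (adjusted p = 0.0201).

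**Figure D1:**
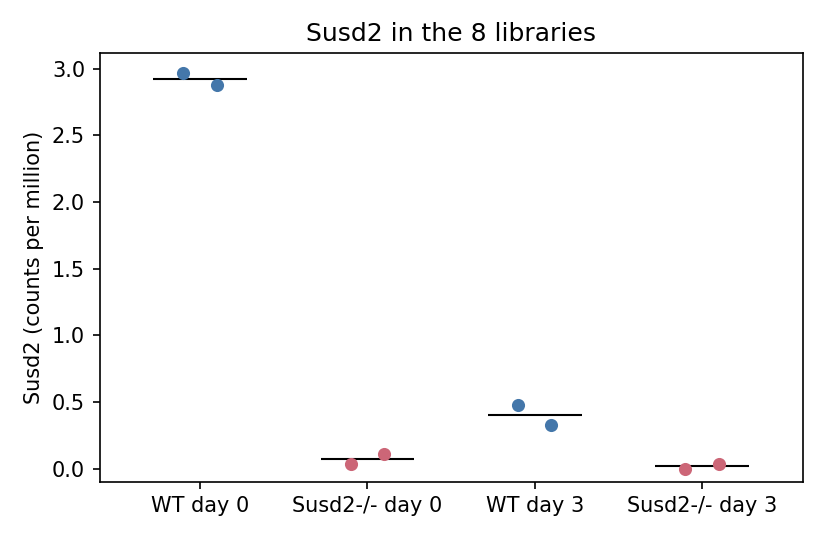
Susd2 in CPM by total counts (y axis) in each of the 8 libraries, by genotype and day (x axis). Points are libraries and bars are means of the 2 libraries of a group, and the WT day 0 libraries stand at 2.97 and 2.88 while every Susd2-/- library is at or below 0.112.

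The first comparison asked how resting CD8+ T cells without Susd2 differed from WT cells before stimulation. Genes that T cells switch on within minutes to hours of receptor or stress signals were higher in Susd2-/- cells (20 of 27), as were genes of mitosis (32 of 35), while cytosolic ribosomal protein genes (44 of 50) and 23 of 42 oxidative phosphorylation genes were lower. With a correlation between genes estimated from the data, camera called the mitosis list (adjusted p = 0.0251) but not the immediate early (adjusted p = 0.196), ribosomal protein (adjusted p = 0.462) and oxidative phosphorylation lists (adjusted p = 0.462). Fos, a subunit of the AP-1 transcription factor, rose from 219 ± 2.83 to 551 ± 19.8 CPM (SD, n = 2), and Mki67, a marker of cycling cells, rose from 67.3 ± 0.657 to 143 ± 12.1 CPM. Rpl30, a protein of the large ribosomal subunit, fell from 924 ± 19.7 to 549 ± 27.5 CPM. In all, 3792 of 16057 genes changed, of which 1848 rose and 1944 fell, and 544 of them changed at least 2-fold (348 higher, 196 lower).

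Of 27 measured immediate early and stress genes 20 rose and 7 did not pass (22 rose and 1 fell adjusted over the list alone). Their median log2 fold change was 0.73, and camera gave an adjusted p of 1.43e-12, with adjusted p = 0.196 with an estimated correlation. Klf6 and Dusp1, a transcription factor and a phosphatase of MAP kinases, rose from 429 ± 2.41 to 1020 ± 31.8 CPM and from 151 ± 1.98 to 386 ± 17.5 CPM (adjusted p = 1.01e-10 and 2.99e-10). Atf3 rose from 0.685 to 6.29 CPM, Fosb from 12.3 to 81.4 CPM and Klf4 from 3.82 to 20.1 CPM. Of 29 T cell activation genes 18 rose and 1 fell (19 and 2 adjusted over the list alone; camera adjusted p = 3.29e-06, adjusted p = 0.235 with an estimated correlation). Those that rose included Nr4a1, a nuclear receptor induced by receptor signalling (81.3 ± 1.17 to 217 ± 5.73 CPM), the phosphatase gene Dusp5 (58.8 ± 4.11 to 194 ± 2.24 CPM), Irf4 (by 1.49 on the log2 scale) and Cd69, an early activation antigen (279 to 529 CPM).

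Of 35 G2 and mitosis genes 32 rose and 3 did not pass (32 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 1.52e-17). This was the list whose camera call held with an estimated correlation (adjusted p = 0.0251). Cenpa, the centromeric histone, rose by 1.20 ± 0.0751 log2 units, Foxm1, a transcription factor of G2 genes, rose from 8.09 to 18.9 CPM and Top2a from 73.9 to 118 CPM. Levels in WT cells at day 3 were 252 CPM for Cenpa and 1090 CPM for Top2a. Of 37 DNA replication genes 18 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 8.04e-06, adjusted p = 0.382 with an estimated correlation), among them Rrm2, Cdc6 and Uhrf1 by 0.87, 1.08 and 0.64 log2 units.

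Of 50 cytosolic ribosomal protein genes 44 fell and 6 did not pass (47 adjusted over the list alone), with a median of -0.53. Camera gave an adjusted p of 6.6e-20, and adjusted p = 0.462 with an estimated correlation, which was 0.782 for this list. Rpl7 fell from 2350 ± 36.9 to 1480 ± 86.9 CPM and Rpl26 from 1340 ± 10.2 to 777 ± 70.2 CPM. Of 42 oxidative phosphorylation genes 23 fell (26 adjusted over the list alone; camera adjusted p = 6.56e-06, adjusted p = 0.462 with an estimated correlation), among them Cox7b (77.0 to 50.8 CPM), Ndufv2 and Ndufa4. Of 13 mitochondrially encoded genes 4 fell (7 adjusted over the list alone; camera adjusted p = 0.00299, adjusted p = 0.625 with an estimated correlation), including mt-Co1 (9030 ± 170 to 6660 ± 187 CPM) and mt-Nd1. In 31 cytotoxic effector genes 13 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 0.0176, adjusted p = 0.462 with an estimated correlation). The proteases Gzma and Gzmb fell from 62.0 to 33.7 CPM and from 25.4 to 14.3 CPM, and the receptor gene Klrk1 from 61.0 to 36.8 CPM.

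**Figure D2:**
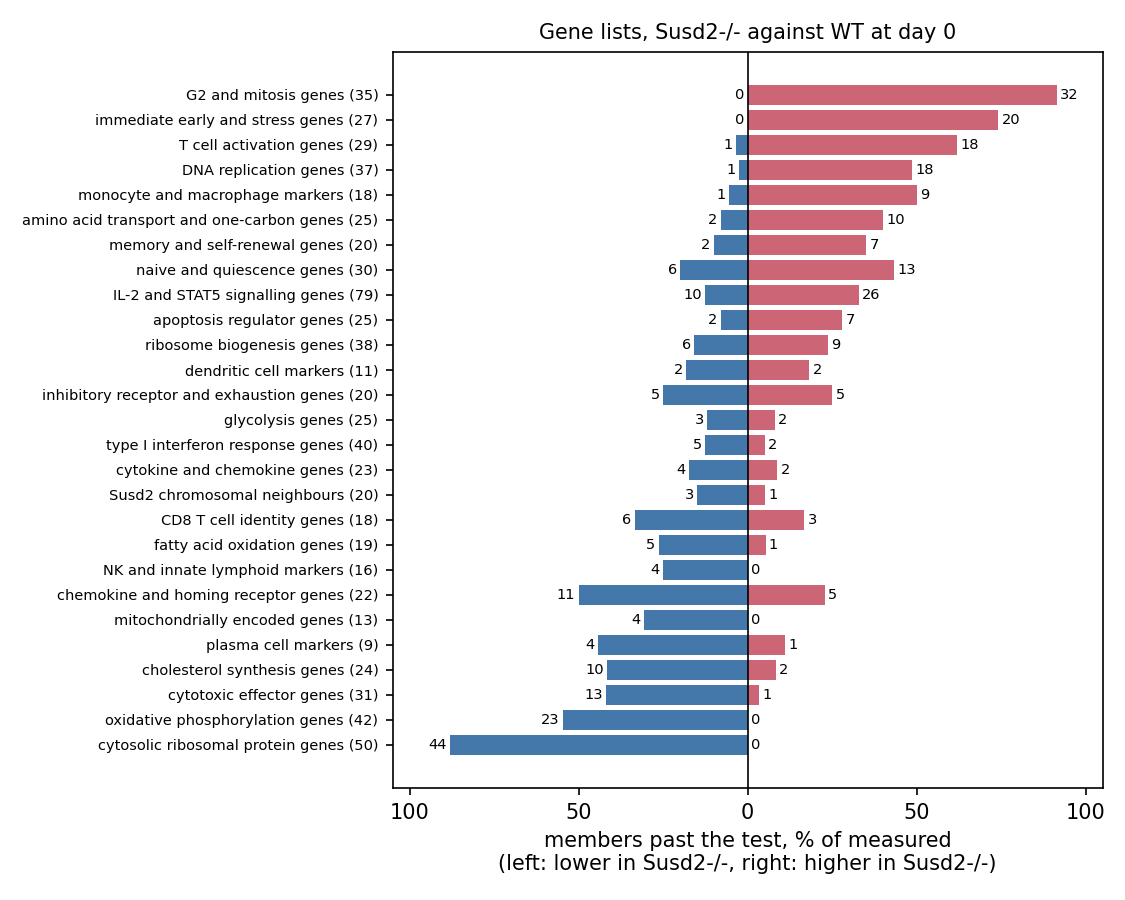
Gene lists with at least 4 members past the edgeR test in Susd2-/- against WT at day 0. Bars give the share of measured members (number in brackets) that was lower (left, blue) or higher (right, red) in Susd2-/- cells, with the number of genes at the bar's end, from 32 of 35 G2 and mitosis genes higher to 44 of 50 cytosolic ribosomal protein genes lower.

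Lists of nutrient, metabolic and ribosome biogenesis genes had members called in both directions. Of 25 amino acid transport and one-carbon genes 10 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.00538, adjusted p = 0.462 with an estimated correlation), and the amino acid transporter genes Slc38a2, Slc1a5 and Slc3a2 rose by 0.81, 0.50 and 0.52. Of 19 fatty acid oxidation genes 5 fell and 1 rose (6 and 1 alone; camera adjusted p = 0.0357, adjusted p = 0.462 with an estimated correlation), with Hadhb at -0.43. The camera test did not call the lists that follow. Of 24 cholesterol synthesis genes 10 fell and 2 rose (12 and 3 adjusted over the list alone), Sqle falling and Insig1 rising. Of 25 glycolysis genes 2 rose and 3 fell (2 and 3; median 0.02, mean -0.04), P4ha1 rising from 43.0 to 63.2 CPM. Of 38 ribosome biogenesis genes 9 rose and 6 fell (10 and 6).

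Lists of T cell differentiation went both ways, and the median and mean had opposite signs for inhibitory receptor and exhaustion genes (-0.27 and 0.05), cytokine and chemokine genes (-0.27 and 0.02) and apoptosis regulator genes (-0.01 and 0.18). Of 30 naive and quiescence genes 13 rose and 6 fell, the same numbers adjusted over the list alone. Klf2 and Ccr7, which direct recirculation through lymphoid organs, rose from 657 to 1070 CPM and from 470 to 693 CPM, while Igfbp4 and Dapl1 fell. Of 20 memory and self-renewal genes 7 rose and 2 fell (7 and 2 alone), with Myb and the IL-2 receptor gene Il2rb rising by 1.17 and 0.59. Of 79 IL-2 and STAT5 signalling genes 26 rose and 10 fell (26 and 12 alone), Maff rising by 2.12 and Cd48 falling from 202 to 99.4 CPM. Of 20 inhibitory receptor and exhaustion genes 5 rose and 5 fell (6 and 5 alone), and Ctla4, Tigit and Nr4a2 rose by 1.43, 1.78 and 2.50. Of 22 chemokine and homing receptor genes 5 rose and 11 fell (5 and 13 alone), Gpr183 rising from 38.5 to 78.0 CPM and Cxcr6, Itgb1 and S1pr4 falling. Of 23 cytokine and chemokine genes 2 rose and 4 fell (2 and 4 alone), with Tnfsf11 rising from 0.921 to 2.65 CPM and Ccl5 falling from 141 to 80.1 CPM. Of 25 apoptosis regulator genes 7 rose and 2 fell (7 and 4 alone), and the rising ones included Bcl2l11, which encodes the death protein BIM (82.6 to 135 CPM), Tnfrsf10b and Cdkn1a. Of 40 type I interferon response genes 2 rose and 5 fell, also adjusted over the list alone. Ly6a, the Sca-1 antigen, fell from 76.1 ± 0.478 to 14.8 ± 0.658 CPM, while Oas2 rose from 38.1 to 61.2 CPM.

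Markers of other spleen cells also differed at day 0. Of 18 monocyte and macrophage markers 9 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00164, adjusted p = 0.382 with an estimated correlation). Vcam1, Apoe and Csf1r were 11.5, 18.9 and 9.66 CPM in WT cells and 32.5, 45.6 and 23.0 CPM in Susd2-/- cells, in the same libraries in which immediate early and mitosis genes were higher, and Ctss fell from 169 to 102 CPM. Of 3 neutrophil markers 1 rose (1 alone; camera adjusted p = 0.0273, adjusted p = 0.382 with an estimated correlation). Of 16 NK and innate lymphoid markers 4 fell (4 alone; camera adjusted p = 0.0428, adjusted p = 0.382 with an estimated correlation), Klra9 going from 8.88 to 3.19 CPM in the libraries in which cytotoxic effector genes were lower. Of 9 plasma cell markers 4 fell and 1 rose (4 and 3 alone), the median log2 fold change lying above 0 and the mean below, with Igha falling from 24.7 to 4.46 CPM and Jchain from 9.84 to 2.08 CPM. Camera did not call this list, nor those that follow. Of 9 gamma-delta T cell markers 1 rose, Cd163l1, and 2 fell, Trgc2 among them (2 and 4 alone). Of 20 B cell markers 2 rose (2 alone), Ighm from 493 to 592 CPM. Cd163l1 lost its call without any 1 of the 4 day 0 libraries and Ighm without either WT library or Susd2-/- library 3. Of 11 dendritic cell markers 2 rose and 2 fell (2 and 2 alone), of 8 mast cell and basophil markers 1 rose (1 alone), and of 7 erythroid markers 1 rose and 1 fell (2 and 1 alone). In edgeR 0 of 12 CD4 and regulatory T cell markers passed, also alone, with 3 at an unadjusted p below 0.05 and 1 each past DESeq2 and limma voom. For 9 megakaryocyte and platelet markers, 3 stromal and endothelial markers and Xist, the measured member of the Y-linked and Xist list, 0 passed in edgeR, alone, at an unadjusted p below 0.05, in DESeq2 and in limma voom.

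Of 18 CD8 T cell identity genes 3 rose and 6 fell (5 and 6 adjusted over the list alone), with a median of -0.05, and Cd3g, Cd3d and Trbc2 fell by 0.41, 0.34 and 0.40 on the log2 scale. Of 8 OT-I receptor V segments 1 fell, also alone, Trbv12-1 going from 683 to 471 CPM. Of 20 chromosomal neighbours of Susd2 1 rose and 3 fell (1 and 2 alone). These were Smarcb1 at 0.26 and Snrpd3, Gucd1 and Gstt2 at -0.30, -0.53 and -0.31. Smarcb1 and Gstt2 lost the call without any 1 of the 4 day 0 libraries, and Snrpd3 and Gucd1 without WT library 4 or Susd2-/- library 4 of day 0.

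The genes of largest change at day 0 were mostly of low level. Vegfa rose from 0.198 to 1.47 CPM, Chl1 from 0.0967 to 0.685 CPM, Plk2 from 3.62 to 18.3 CPM, Rhob from 20.5 to 94.9 CPM and Dusp4 from 3.43 to 15.9 CPM. Tln2 had 0 counts in the WT libraries and 13 in the Susd2-/- libraries, at least 4.36-fold higher against a floor of 3 counts over the group. Lrrc49 had 9 and 0 counts, at least 2.98-fold lower. The WT level of Etv4 was 11.7% of the Susd2-/- level (2 against 17 counts, 95% interval for independent counts 1.31% to 49.2%), and the Susd2-/- level of Slc9b2 was 8.39% of the WT level (1 against 12 counts, 0.196% to 56.7%). Iigp1, an interferon-induced GTPase, fell from 41.6 ± 3.01 to 2.17 ± 1.04 CPM, Klra5 from 7.65 to 1.17 CPM and Casp1 from 11.1 to 2.35 CPM. Calls were lost without 1 of the day 0 libraries for Etv4 (WT library 4 or Susd2-/- library 3), Lrrc49 (WT library 3 or either Susd2-/- library) and Slc9b2 (WT library 4 or either Susd2-/- library).

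The count of day 0 changes rested on the day 0 libraries. It was 2044 and 2088 without WT library 3 or 4, 2342 and 2104 without Susd2-/- library 3 or 4, and 725 with the day 0 libraries of each group counted as 1 (360 higher, 365 lower). That fit sets 1 sample against 1 at day 0 and takes its spread from the day 3 libraries. A fit of the 4 day 0 libraries alone, which leaves out the larger spread of day 3, called 5627 genes. The spread in that fit may be technical, as the labels do not say that the libraries came from separate mice.

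**Figure D3:**
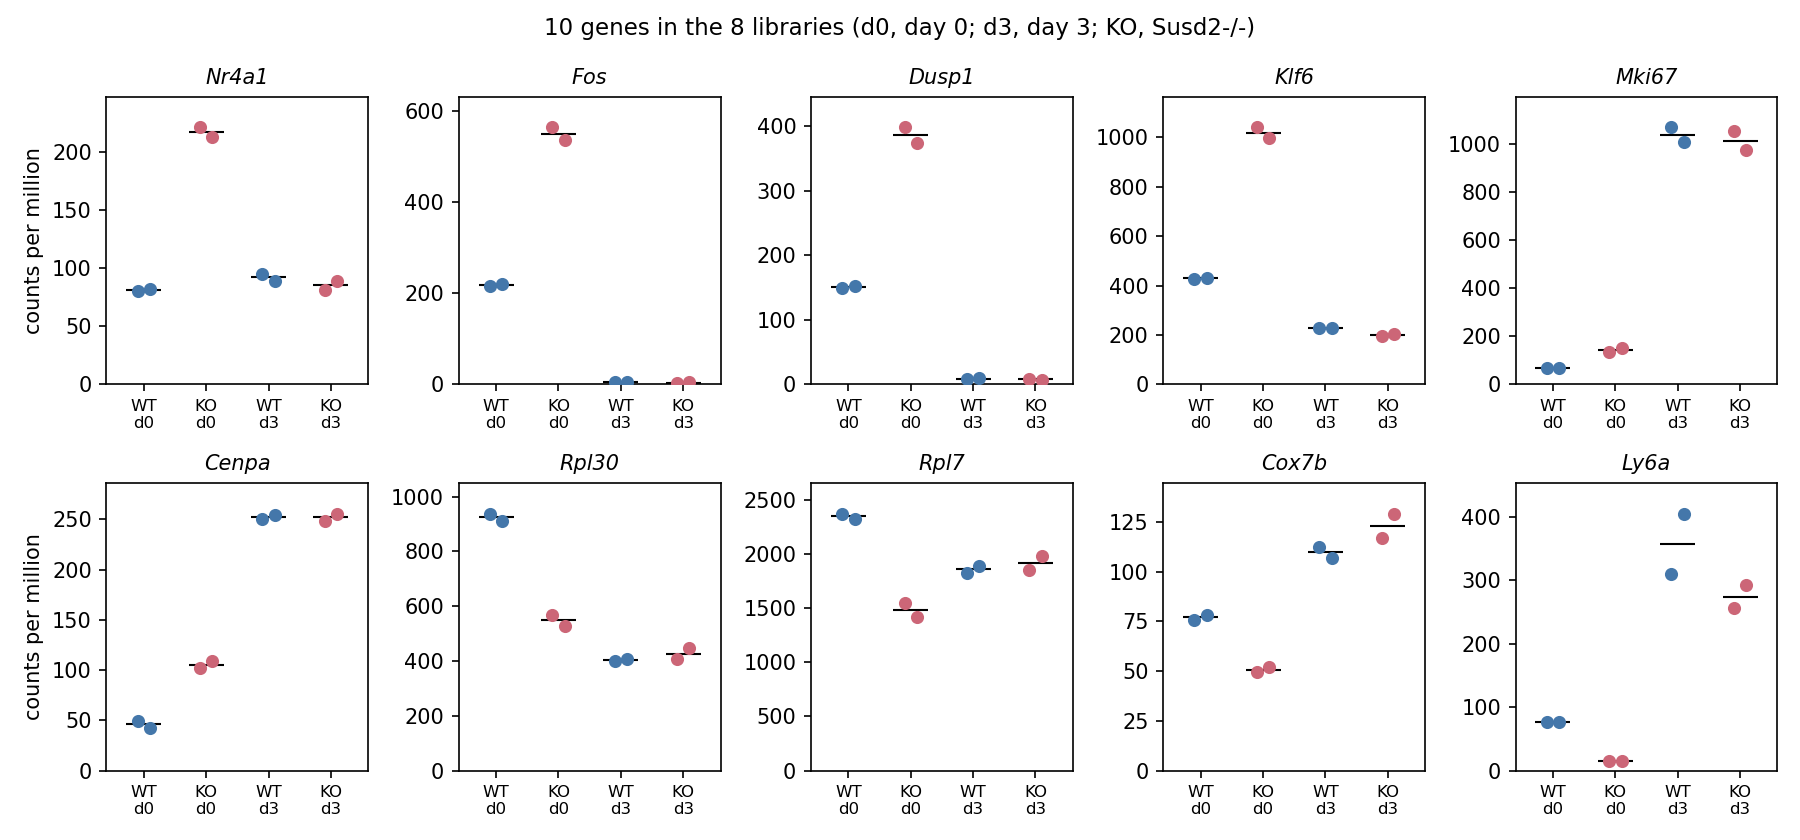
CPM by TMM-scaled library size (y axes, each from 0) for 10 genes named in the text in each of the 8 libraries, by group (x axes). Points are libraries and bars are means of the 2 libraries of a group, and at day 0 both Susd2-/- libraries lie above both WT libraries for Nr4a1, Fos, Dusp1, Klf6, Mki67 and Cenpa and below them for Rpl30, Rpl7, Cox7b and Ly6a.

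The second comparison asked how Susd2-/- cells differed from WT cells after 3 days with the peptide. Few genes did, and camera did not call the memory and self-renewal (adjusted p = 0.327), naive and quiescence (adjusted p = 0.437) or apoptosis regulator lists (adjusted p = 0.634). Eomes and Tcf7, transcription factors of memory T cells, fell from 9.98 ± 0.0957 to 6.14 ± 0.307 CPM and from 118 ± 10.1 to 93.2 ± 1.23 CPM, and Txk, a T cell kinase gene, fell from 7.28 to 4.57 CPM. Bcl2l11 rose from 18.3 ± 1.18 to 26.5 ± 3.24 CPM and Spry2, an inhibitor of growth factor signalling, from 12.9 ± 3.56 to 26.0 ± 2.65 CPM. In all, 22 of 16057 genes changed, 8 up and 14 down, with 9 of them at least 2-fold and 1267 genes at an unadjusted p below 0.05. The joint fit gave each gene 1 spread for both days, although the spread was larger at day 3 (10.1%) than at day 0 (5.38%). Its p-values at day 3 may therefore be too small. A fit of the 4 day 3 libraries alone, with fewer libraries to estimate the spread, called 3 genes.

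Igf2bp3, an RNA-binding protein gene, rose from 9.27 to 20.9 CPM (1.17 ± 0.167, adjusted p = 0.00585), Nsg2 from 1.61 to 2.88 CPM and Nnt, the mitochondrial transhydrogenase gene on chromosome 13 at 119335448 to 119408997, from 14.6 to 24.2 CPM. Mid1, on chromosome X at 169685199 to 170005736, fell from 4.34 to 0.777 CPM (-2.53 ± 0.338, adjusted p = 0.00368). Lmna, the lamin A gene, fell from 6.25 to 2.59 CPM, and Cul9, Ulbp1, Fam189b, Mvp, Pim3, Pcyt1a and Furin fell by 1.00, 0.60, 0.54, 0.53, 0.41, 0.41 and 0.39 on the log2 scale. H2-Q6, an MHC class Ib gene on chromosome 17 with near-identical neighbours, fell from 163 to 61.1 CPM. mt-Nd3, on the mitochondrial genome at 9459 to 9806, fell from 4.38 to 0.984 CPM. The remaining 3 genes, chosen after their values were seen, rose and are pseudogenes: Gm28438 (chromosome 1, 24612775 to 24613119; 0.337 to 13.5 CPM), Gm10222 (0.552 to 2.62 CPM) and Tmem181b-ps (4.85 to 10.3 CPM). Counts of mt-Nd3, Gm28438, Gm10222 and H2-Q6 are uncertain because their transcripts have near-identical copies.

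At day 3 camera called 3 lists, none of them with an estimated correlation or in fry. It called 5 without WT library 1 of day 3 and 2 without WT library 2 of day 3. Of 24 cholesterol synthesis genes 0 passed in edgeR (2 rose adjusted over the list alone, 8 were higher at an unadjusted p below 0.05, 1 was higher in DESeq2 and 0 passed in limma voom). Their median was 0.16 and the camera adjusted p was 0.00391, with adjusted p = 0.948 with an estimated correlation. Of 40 type I interferon response genes 0 passed in edgeR (2 lower alone, 8 lower at an unadjusted p below 0.05, 2 lower in DESeq2, 0 in limma voom), with a median of -0.29 and a camera adjusted p of 0.00281 (adjusted p = 0.948 with an estimated correlation). WT library 2 stood apart in this list: Isg15 was 24.2 and 67.9 CPM in the WT libraries and 29.9 and 23.4 CPM in the Susd2-/- libraries. The mean log2 CPM of the list was 3.32 and 4.15 in WT libraries 1 and 2 and 3.47 and 3.36 in the Susd2-/- libraries. Both Susd2-/- libraries thus lay above WT library 1, so the negative median rested on WT library 2. Of 27 immediate early and stress genes 0 passed in edgeR (3 lower alone, 8 lower and 1 higher at an unadjusted p below 0.05, 1 lower in DESeq2, 0 in limma voom), with a median of -0.19 and a camera adjusted p of 0.012 (adjusted p = 0.948 with an estimated correlation). Among 35 G2 and mitosis genes and 50 cytosolic ribosomal protein genes 0 passed in edgeR, alone, at an unadjusted p below 0.05, in DESeq2 or in limma voom, and their medians were 0.02 and 0.02.

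The count at day 3 was unstable. It was 309 without WT library 1, 59 without WT library 2, 392 without Susd2-/- library 1, 12 without Susd2-/- library 2, and 49, 14, 18 and 6 without WT library 3 or 4 or Susd2-/- library 3 or 4 of day 0, and only Gm28438, Igf2bp3 and Mid1 were called in all 8 of these fits. Of the 22 genes, 20, 13, 21 and 6 were among the calls without WT library 1 or 2 or Susd2-/- library 1 or 2 of day 3, and 20, 13, 16 and 6 without WT library 3 or 4 or Susd2-/- library 3 or 4 of day 0. DESeq2 called 66 genes, with the 22 among them, limma voom 19 with 10 of the 22, the fit with the library number as a block 17 with 10, lane 1 alone 16 with 8, lane 2 alone 16 with 4 and a fit of the 4 day 3 libraries alone 3 with 2. Tcf7, Eomes and Bcl2l11 did not pass in limma voom, with lane 1 or lane 2 alone or with the 4 day 3 libraries alone, and Tcf7 and Eomes did not pass with the library number as a block.

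Another comparison asked whether the same genes differed between genotypes before and after stimulation. Of the 22 genes called at day 3, 13 were also called at day 0. Of these, 5 were higher on both days (Bcl2l11, Igf2bp3, Nnt, Gm28438 and Tmem181b-ps), 4 were lower on both days (Cul9, Fam189b, H2-Q6 and mt-Nd3), and 4 were higher at day 0 and lower at day 3 (Furin, Lmna, Pcyt1a and Pim3). Independent lists would share 2.62 genes in the same direction, against 9 found, and the overlap of 13 had p = 0.000383 (two-sided Fisher's exact test across genes, which are not independent). The count of 9 was 14 without WT library 3 of day 0, 4 without Susd2-/- library 4 of day 0, 96 and 17 without WT library 1 or 2 of day 3 and 41 without Susd2-/- library 1 of day 3. At an unadjusted p below 0.05, 245 genes were shared in the same direction, against 219 for independent lists, and 287 were shared in opposite directions. Opposite directions were thus the more frequent, and the number that independent lists would share in them was not computed. Both comparisons take each gene's spread from 1 fit, so the lists are not independent even without an effect. The Fisher p and the numbers for independent lists are therefore a rough guide only. The interaction passed for the 4 genes of opposite direction and for Gm28438 (adjusted p = 0.00265), and not for the other 8, for example Nnt (0.76 ± 0.14 at day 0 and 0.72 ± 0.14 at day 3, interaction adjusted p = 0.933).

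**Figure D4:**
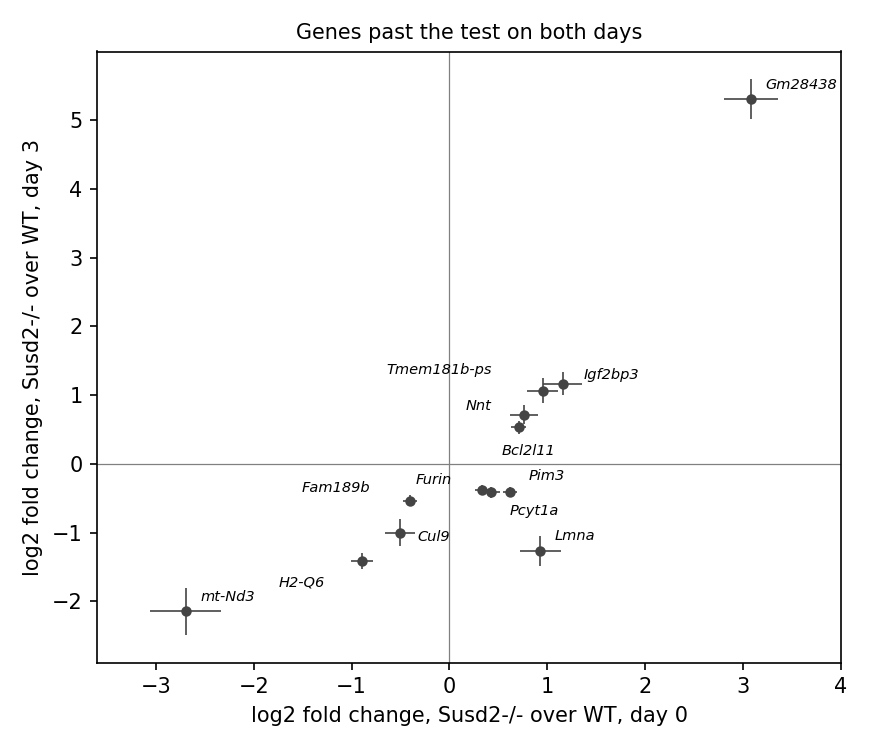
Log2 fold change of Susd2-/- over WT at day 0 (x axis) and at day 3 (y axis) for the 13 genes past the edgeR test on both days. Points are estimates and bars are standard errors, and 9 genes lie in the quadrants of one direction and 4 (Furin, Lmna, Pcyt1a and Pim3) in the quadrant of higher at day 0 and lower at day 3.

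The day comparison in WT cells asked how cells after 3 days with the peptide differed from untreated cells. No group was cultured without the peptide. Effects of the peptide, of time in culture and of a loss of other spleen cells therefore cannot be told apart in either genotype. Of the naive and quiescence genes 26 of 30 fell (camera adjusted p = 1.52e-08, adjusted p = 0.164 with an estimated correlation), and 35 of 35 G2 and mitosis genes rose. Klf2, the factor that maintains quiescence, fell from 657 ± 4.92 to 0.703 ± 0.193 CPM, and its target S1pr1, the receptor for exit from lymphoid organs, from 567 ± 3.15 to 5.88 ± 0.237 CPM. Il2ra, the high-affinity chain of the IL-2 receptor, rose from 2.53 ± 0.348 to 982 ± 14.2 CPM and the granzyme gene Gzmb from 25.4 ± 0.814 to 6300 ± 319 CPM. Of 16057 genes 12073 changed, 5805 up and 6268 down, and 7973 of them at least 2-fold. The median of all genes was -0.14, and with total counts in place of TMM it was -0.32, so changes near these sizes depend on the scaling.

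Of 30 naive and quiescence genes 26 fell and 1 rose (26 and 1 adjusted over the list alone; camera adjusted p = 1.52e-08, adjusted p = 0.164 with an estimated correlation). Of 20 memory and self-renewal genes 13 fell and 5 rose (13 and 5 alone; camera adjusted p = 0.0394, adjusted p = 0.207 with an estimated correlation), including Il7r (612 to 74.1 CPM) and Tcf7 (1100 to 118 CPM). Of 29 T cell activation genes 21 rose and 5 fell (21 and 5 alone; camera adjusted p = 5.57e-05, adjusted p = 0.164 with an estimated correlation), Irf4 rising by 5.41 on the log2 scale, to 556 CPM. Of 31 cytotoxic effector genes 17 rose and 13 fell (17 and 13 alone; camera adjusted p = 0.398), Tbx21 rising from 16.1 to 113 CPM and Gzma falling from 62.0 to 1.02 CPM. Of 23 cytokine and chemokine genes 16 rose and 6 fell (16 and 6 alone; camera adjusted p = 0.0137, adjusted p = 0.164 with an estimated correlation), Lif rising from 1.88 to 260 CPM and Ccl5 falling from 141 to 4.65 CPM. Il3 had 0 counts at day 0 and rose by at least 261-fold. Pdcd1, which encodes PD-1, rose from 1.79 to 192 CPM and Ctla4 from 16.5 to 446 CPM, and the integrin genes Itgae and Itgb7 fell from 174 to 0.756 CPM and from 706 to 50.3 CPM.

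All 35 G2 and mitosis genes and all 37 DNA replication genes rose (35 and 37 adjusted over the list alone), with camera adjusted p = 1.51e-15 for each. With an estimated correlation these were adjusted p = 0.0319 for the G2 and mitosis genes and adjusted p = 0.164 for the DNA replication genes. Ccna2 rose from 7.74 to 311 CPM and Mcm10 from 2.86 to 194 CPM. All 38 ribosome biogenesis genes rose (38 alone; camera adjusted p = 1.15e-12, adjusted p = 0.207 with an estimated correlation), with Ncl going from 873 to 5560 CPM, while 41 of 50 cytosolic ribosomal protein genes fell and 2 rose (41 and 2 alone; camera adjusted p = 1.4e-05, adjusted p = 0.539 with an estimated correlation). Their median of -0.61 lay below that of all genes (-0.14) with TMM. Another scaling moves both medians alike, so this is no check on the scaling. Of 25 glycolysis genes 24 rose and 1 fell (24 and 1 alone; camera adjusted p = 1.98e-08, adjusted p = 0.207 with an estimated correlation), Tpi1 from 51.5 to 1530 CPM and Pgk1 from 167 to 2070 CPM. Of 42 oxidative phosphorylation genes 40 rose (40 alone; camera adjusted p = 1.93e-09, adjusted p = 0.219 with an estimated correlation), Cycs from 45.9 to 242 CPM. Of 13 mitochondrially encoded genes 6 fell (4 alone; camera adjusted p = 0.0732), mt-Co1 from 9030 to 4800 CPM, but with a trend on transcript length and GC content removed 2 fell and 7 rose. Of 24 cholesterol synthesis genes 21 rose (22 alone; camera adjusted p = 2.11e-07, adjusted p = 0.207 with an estimated correlation), and of 25 amino acid transport and one-carbon genes 22 rose and 2 fell (22 and 2 alone; camera adjusted p = 3.95e-07, adjusted p = 0.164 with an estimated correlation), Slc7a5 from 33.8 to 489 CPM. Of 40 type I interferon response genes 26 fell and 3 rose (26 and 3 alone; camera adjusted p = 0.00233, adjusted p = 0.651 with an estimated correlation), Oas2 from 38.1 to 0.669 CPM.

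The genes of largest change from day 0 to day 3 in WT cells were at 0 counts on one of the days, and folds are bounds against a floor of 3 counts over the group. Acsl6, an acyl-CoA synthetase gene, was at least 1680-fold higher at day 3 (0 to 81.9 CPM), Dclk1 at least 975-fold, Slc1a2 at least 313-fold and Pla1a at least 301-fold higher. Ccr9, the gut homing receptor, was at least 3760-fold lower (191 to 0 CPM), Fcgrt at least 672-fold and Lcn4 at least 367-fold lower. Vcam1, on the list of monocyte and macrophage markers, was at least 225-fold lower. Of 18 monocyte and macrophage markers 17 fell (17 alone; camera adjusted p = 8.11e-06, adjusted p = 0.164 with an estimated correlation) and of 16 NK and innate lymphoid markers 14 fell and 1 rose (14 and 1 alone; camera adjusted p = 0.00143, adjusted p = 0.164 with an estimated correlation), Cd7 going from 117 to 0.152 CPM. Of 18 CD8 T cell identity genes 14 fell and 3 rose (14 and 3 alone; camera adjusted p = 0.00716, adjusted p = 0.429 with an estimated correlation), Cd8b1 falling from 974 to 304 CPM.

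The same comparison in Susd2-/- cells gave 12272 changed genes, 5891 up and 6381 down. Klf2 fell from 1070 ± 92.4 to 0.846 ± 0.196 CPM and S1pr1 from 658 ± 29.5 to 6.31 ± 0.261 CPM. Among genes at 0 counts on one of the days, Dclk1 was at least 1170-fold higher and Il3 at least 156-fold higher at day 3. Vcam1 was at least 872-fold lower, Slc40a1, the iron exporter gene, at least 482-fold lower, and C1qa and C1qb, complement genes of macrophages, at least 282-fold and 283-fold lower. The day 3 level of Ccr9 was 0.0179% of its day 0 level (3 against 12673 counts, 95% interval for independent counts 0.00369% to 0.0523%). Of 18 monocyte and macrophage markers 18 fell (18 alone; camera adjusted p = 1.55e-06, adjusted p = 0.18 with an estimated correlation). Of 50 cytosolic ribosomal protein genes 12 rose and 21 fell (12 and 21 alone; camera adjusted p = 0.424), and of 27 immediate early and stress genes 21 fell and 5 rose (21 and 5 alone; camera adjusted p = 0.00142, adjusted p = 0.199 with an estimated correlation).

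Across genes, the log2 fold changes of the 2 genotypes had a Pearson correlation of 0.902 over 16057 genes and 0.976 over the 5920 genes with an average log2 CPM of at least 5, where genes are not independent replicates. In both genotypes 10634 genes changed in the same direction and 86 in opposite directions, with 1353 called in WT alone and 1552 in Susd2-/- cells alone. The test of the difference is the interaction, which called 2164 genes, 1059 with a more positive and 1105 with a more negative response in Susd2-/- cells, and 358 of them at least 2-fold. For most of the leading interaction genes the genotypes were apart at day 0 and close at day 3. Sik1, a kinase gene induced by cAMP, was at 76.9 and 307 CPM in WT and Susd2-/- cells at day 0 and at 69.4 and 62.6 CPM at day 3 (interaction -2.15 ± 0.0898, adjusted p = 4.76e-11). Tnfaip3, which encodes the NF-kB inhibitor A20, was at 620 and 1740 CPM at day 0 and at 32.7 and 30.8 CPM at day 3, and the clock gene Per1 at 59.8 and 187 CPM and then 46.7 and 43.9 CPM. The noncoding transcript AW112010 went the other way, with 103 and 35.5 CPM at day 0 and 141 and 158 CPM at day 3 (1.70 ± 0.101, adjusted p = 5.05e-09).

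By list, the interaction was negative for 18 of 27 immediate early and stress genes (20 alone; camera adjusted p = 3.49e-14, adjusted p = 0.157 with an estimated correlation) and for 27 of 35 G2 and mitosis genes (31 alone; camera adjusted p = 7.03e-16, adjusted p = 0.0306 with an estimated correlation). It was positive for 40 of 50 cytosolic ribosomal protein genes (44 alone; camera adjusted p = 6.44e-18, adjusted p = 0.516 with an estimated correlation) and for 16 of 42 oxidative phosphorylation genes (25 alone; camera adjusted p = 3.5e-06, adjusted p = 0.516 with an estimated correlation). It was negative for 2 and positive for 1 of 18 monocyte and macrophage markers (4 and 1 alone; camera adjusted p = 0.00159 for a negative shift, adjusted p = 0.369 with an estimated correlation), Apoe at -1.43 and Ctss at 0.57. Of 3 neutrophil markers 0 passed in edgeR, alone, at an unadjusted p below 0.05, in DESeq2 or in limma voom, with a camera adjusted p of 0.0398 (adjusted p = 0.369 with an estimated correlation). Eomes and Tcf7 had negative interactions of -0.83 ± 0.175 and -0.49 ± 0.0925, with means of 26.8 and 29.4 CPM for Eomes in WT and Susd2-/- cells at day 0. The interaction count was 1305 and 1176 without WT library 3 or 4 of day 0, 1440 and 1262 without Susd2-/- library 3 or 4 of day 0, 364 with the day 0 libraries of each group counted as 1, and 1187 with lane 2 alone.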

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

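Tests on CD8 T cell identity genes, macrophage markers, fold changes between single libraries, the calls left with a length and GC trend removed, the distance from 0 of the matched difference of immediate early genes, the handling of the day 0 libraries, DNA next to Susd2 and opposite directions were chosen only after the results were seen, as was the fit with the day 0 libraries of each group counted as 1. The test of the interaction itself singled out 2164 genes whose response over 3 days differed between WT and Susd2-/- cells. The 10 of smallest adjusted p among the nameable genes had interactions of -2.15 (Sik1), -3.34 (Atf3), -1.44 (Klf6), 1.70 (AW112010), -1.86 (Dusp5), -1.53 (Nr4a1), -1.73 (Per1), -1.57 (Tnfaip3), -1.58 (Irf4) and -1.62 (Jun). This comparison shares its libraries with the one at day 0, so it is no separate evidence for the day 0 differences.

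Immediate early and mitosis genes were higher and ribosomal protein genes lower in Susd2-/- cells at day 0. Against genes matched on transcript length, GC content and level, differences of 0.64 ± 0.21, 0.79 ± 0.0653 and -0.37 ± 0.0454 stayed for immediate early, mitosis and ribosomal protein genes. These were 88.2%, 104% and 69.6% of the lists' own medians. Here and for the medians below, ± gives a standard error of the median over the genes of a list. It treats genes as independent and holds no spread between libraries, so it may be too small. With a length and GC trend removed 21 of 27, 32 of 35 and 43 of 50 were still called in that direction. Both results argue against such a bias as the whole cause. For immediate early genes the bound written before the test (more than 50% kept, by 2 SE) was not met. Genes matched to the ribosomal protein genes had a median of -0.11. A part from bias stays open for immediate early and ribosomal protein genes. Fewer T cells would lower T cell genes by about as much as ribosomal protein genes, and the CD8 identity median was -0.048 ± 0.0663 against -0.53. These identity genes went both ways, with 6 higher and 6 lower at an unadjusted p below 0.05. The 8 OT-I receptor V segments, 1 of them lower at that threshold, had a median of -0.44. The answer thus depends on the list of T cell genes, and a part from fewer T cells stays open. Genes near 0 in WT cells at day 0 and abundant at day 3 implied 0.0567% of day 3-like cells, against 3.03% implied by mitosis genes, so cells with the day 3 profile do not account for the mitosis part, and cycling cells of another stage were not tested. A different handling of the Susd2-/- spleens (immediate early median of -0.19 at day 3, and 2 libraries per day 0 group that may come from 1 preparation) and RNA of macrophages left after bead enrichment (18 markers, median 0.95 ± 0.227, 9 higher and 1 lower, and no measured macrophage level of immediate early genes) cannot be told apart from an effect of the genotype on immediate early genes. For mitosis and ribosomal protein genes too, a preparation effect at day 0 cannot be told apart from a genotype effect. Whether RNA of other spleen cells added to the mitosis genes was not tested.

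Between genotypes, 13 genes were called on both days. DNA of another strain next to Susd2 would place them on chromosome 10, and 0 of them lay within 20 Mb of Susd2. A fixed sequence variant with the same effect in resting and stimulated cells would give 1 direction on both days. This 4 of the genes (Furin, Lmna, Pcyt1a and Pim3) did not have. Their day 3 calls were each lost without some single libraries, and a variant whose effect differs between the days was not tested. For the genes with 1 direction a fixed sequence variant cannot be told apart from an effect of Susd2, because the interaction passed for 1 of the 9 and the comparison holds 1 mutant line. For mt-Nd3 and Gm28438, whose transcripts share 99.7% of bases, reads assigned to one in place of the other may explain the opposite changes, with summed levels of 5.54 and 5.89 CPM at day 0 but 4.71 and 14.5 CPM at day 3.

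Many more genes were called between genotypes at day 0 (3792) than at day 3 (22). A larger spread at day 3 alone with like differences between the genotypes would make fold changes between single libraries larger at day 3, but across 9092 genes their SD was 0.374 to 0.392 at day 0 and 0.196 to 0.272 at day 3, at least 1.38 times as large at day 0, whatever the source of the day 0 differences. Day 0 libraries close to technical repeats could raise the count, and this cannot be told apart from a genotype effect: with those of each group counted as 1 the counts were 725 and 1, but that fit sets 1 sample against 1 at day 0 and takes its spread from the day 3 libraries, so the bound written before its result excludes nothing. A smaller effect of Susd2 in stimulated cells and a preparation effect limited to day 0 both stay open.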

How the results depend on the processing

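The fits with the day 0 libraries of each group counted as 1, with lane 2 alone and with a length and GC trend removed, and the list tests without single libraries, were chosen only after the data were seen. So was the rule that a list's direction is followed only where one direction had at least 3 members and 3 times as many as the other, and lists without such a majority are described by both counts. Without the majority, 48 of 2762 list counts were reversed for lists with at least 3 members called in a direction, and 83 of 3423 for lists with at least 1. Across the alternatives, calls of named genes were the same in 5264 comparisons, lost in 355 and reversed in 0. Counts of list members were within 1.5 times in 1619 comparisons, outside in 148 and reversed in 2 under this rule. These were mitochondrially encoded genes in WT cells from day 0 to day 3 with the length and GC trend removed (2 lower, 7 higher) and plasma cell markers in Susd2-/- cells with receptor segment, mitochondrial and sex-linked genes left out (1 lower, 2 higher). Where no cause is given, the cause was not tested.

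Requiring a 2-fold change left 544 genes at day 0, 9 at day 3, 7973 from day 0 to day 3 in WT cells and 358 in the interaction, and an adjusted p below 0.01 left 2243, 5 and 987 at day 0, at day 3 and in the interaction, as stricter thresholds must. Counting the day 0 libraries of each group as 1 gave 725, 1 and 364, with the spread taken from the day 3 libraries alone, and at day 0 mitosis (26 higher) and ribosomal protein genes (35 lower) were the lists within 1.5 times of their counts. The others moved: immediate early 20 to 12, T cell activation 18 to 11, DNA replication 18 to 9 and macrophage markers 9 to 2 higher, and oxidative phosphorylation 23 to 4 and cytotoxic effector genes 13 to 3 lower, among others. Lanes as separate samples gave 153 genes at day 3 and 3603 in the interaction, lanes in limma voom with the library as a random block 383 at day 3, DESeq2 66, no low-count filter 138 and the 4 day 3 libraries alone 3, and lane 2 alone gave 1187 in the interaction. With the library number as a replicate block the counts were 3406, 17 and 1796. The log2 difference between the 2 libraries of a group, in the order of their numbers, was compared between WT and Susd2-/- cells. The 2 differences correlated by 0.0283 at day 0 and -0.0965 at day 3 across genes, which are not independent. The share of day 0 calls that were higher was 48.7% and ran from 41.2% (length and GC trend removed) to 64% (348 of 544, at least 2-fold), and to 56.6% (total counts) at the same threshold.

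Susd2 at day 3 passed the threshold with lanes as samples (-3.81, adjusted p = 0.0268), with lanes in limma voom (-3.40, adjusted p = 0.0459), without the low-count filter (-3.91, adjusted p = 0.0106) and without WT library 2 of day 3 (-4.17, adjusted p = 0.0201), within a range of adjusted p up to 0.797 with lane 2 alone. With an estimated correlation camera called 1, 0, 1, 1 and 1 lists at day 0, at day 3, in the WT and Susd2-/- day comparisons and in the interaction. fry, which does not compare a list with other genes, called 21 at day 0, 0 at day 3 and 36 in the WT day comparison. Shared genotype calls in 1 direction numbered 245 at an unadjusted p below 0.05, with 287 in opposite directions.

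Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 2044 (without WT library 3 of day 0) to 4410 genes (without WT library 1 of day 3) at day 0 and 6 (without Susd2-/- library 4 of day 0) to 392 (without Susd2-/- library 1 of day 3) at day 3. It gave 1176 (without WT library 4 of day 0) to 2498 (without Susd2-/- library 1 of day 3) in the interaction, 11137 to 12355 in the WT and 11229 to 12757 in the Susd2-/- day comparison. Susd2 ranged from -6.29 to -4.72 at day 0 and from -6.74 to -3.35 at day 3, list calls from 10 to 15 at day 0 and from 2 to 5 at day 3, and shared calls from 4 (without Susd2-/- library 4 of day 0) to 96 (without WT library 1 of day 3). The correlation of the log2 fold changes of the 2 genotypes from day 0 to day 3 ran from 0.852 to 0.864. With all libraries it was higher, at 0.902 over 16057 genes. The fits without 1 library kept more genes, 16951 to 17155. At 0 to 16 counts per library, the level of Susd2 at day 3 is limited by depth.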

Other observations

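The family test over gene symbols, the interferon-inducible GTPases and the genes named in the next sentences were chosen only after the results were seen. The hypothesis on mt-Nd3, Gm28438 and Nnt below was likewise raised from fold changes already seen. Only the prediction of its position test was written before that test's result. The interferon-inducible GTPases, which attack vacuoles of intracellular pathogens and answer mainly to interferon gamma, were lower in Susd2-/- cells at day 0. Of 18 measured members 16 fell, and Gbp9 and Irgc1 did not pass, with a median of -1.04, but the set was put together after falls of its members were seen, so the set itself was not tested. Igtp fell from 194 to 70.4 CPM, Gbp2 from 170 to 69.0 CPM, Tgtp1 from 52.8 to 14.9 CPM, Irgm2 from 62.5 to 26.3 CPM and Ifi47 from 268 to 150 CPM. At day 3 the median was 0.01, and Igtp was at 256 and 255 CPM in WT and Susd2-/- cells. Gbp genes have near-identical copies, so the levels of single members are uncertain.

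Among 149 families of symbols with a common stem, 17 of 298 tests at day 0 passed (one-sided Fisher's exact test). At day 3, with 22 genes called, 0 of 298 passed. The test treats genes as independent, which members of a family may not be, so its p-values may be too small. Families with a larger share of falling members than the 12.1% of all genes included Gbp, part of the GTPases above (9 of 10, adjusted p = 3.65e-06), Psmb, subunits of the proteasome (7 of 10, adjusted p = 0.00138), Mrpl, proteins of the mitochondrial ribosome (17 of 50, adjusted p = 0.00172), and Zfp, zinc finger proteins (81 of 341, adjusted p = 1.22e-07). Families with a larger share of rising members than the 11.5% of all genes included Mcm (7 of 10, adjusted p = 0.00115), a stem that includes subunits of the replicative helicase. Others were Srsf, splicing factors (6 of 11, adjusted p = 0.0159), and Kif, kinesin motors (10 of 29, adjusted p = 0.0215). Klf and Snhg, zinc finger factors and hosts of small nucleolar RNAs, also passed (6 of 13 each, adjusted p = 0.0338).

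A candidate explanation for the genes mt-Nd3, Gm28438 and Nnt is that the Susd2-/- mice carried C57BL/6N alleles and the WT mice C57BL/6J alleles, which the strain label, C57BL/6, leaves open. Nnt, part of which is deleted in C57BL/6J, was higher in Susd2-/- cells by 0.76 and 0.72 log2 units at day 0 and day 3. Along the 99.7% identical transcripts, Gm28438 differed from mt-Nd3 by T3C, counted from 1 at the first base of mt-Nd3, at mitochondrial position 9461, where the substrains are known to differ. Reads with the second allele would then match Gm28438, which rose from 0.6 to 5.13 CPM at day 0 while mt-Nd3 fell from 4.94 to 0.766 CPM. Sequence reads were not analysed here, and the sum of both genes was not equal between genotypes at day 3 (4.71 and 14.5 CPM). If the hypothesis holds, other differences between the genotypes could also come from the substrain, and the counts cannot separate these causes.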
